A study of Drosophila melanogaster with 16 samples.

How the data were processed

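ChIP-seq of γH2Av was carried out on follicle cell nuclei from OregonR wild type and from H2Av[ΔCT] egg chambers at stages 10B and 13, with an antibody raised against the phosphorylated tail. Per the labels' protocols, ovaries came from females fed wet yeast for 2 days, were fixed in 4% formaldehyde, and 3000 egg chambers were collected from each genotype. Each of the 8 groups, ChIP and input for each genotype and stage, had 2 libraries. The labels do not say whether these came from separate collections of animals.

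The authors deposited 1 table per ChIP group, which holds a log2 value for each window, averaged over the 2 replicates according to the labels. Per the submitters' processing notes, Bowtie and bedtools were used with the dm3 build. Versions, filters, scaling between libraries and the constant added before taking logs are not given in the sources used here. That the log2 value is ChIP over input is inferred from the input libraries and from values of both signs. All 4 tables list the same 1687374 windows of 1 kb in steps of 100 bp, of which 1190300 lie on the arms X, 2L, 2R, 3L and 3R.

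Window values fell into separate modes. Most lay near 0, a second group lay near −11 (medians of −10.92, −11.24, −10.77 and −11.29 in WT at stages 10B and 13 and in H2Av[ΔCT] at stages 10B and 13), and a smaller one lay below −15. The second group has the position that an average takes when 1 of the replicates has no reads in a window, and it is called windows without reads. Their removal also took out windows at exactly 0 and those above 5, the latter at most 0.0360% of arm windows in a track. A value of exactly 0 filled all of the unplaced sequences U and Uextra (100% of windows), which were left out, and 12.2% of windows on the heterochromatic arms in WT at stage 10B. A mean over a 5 kb bin is pulled down by windows without reads, so sparse coverage lowers a track in the main values. Read counts and depths were not analysed here, and the share of windows without reads is the only measure of depth.

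Windows were averaged in 5 kb bins by window midpoint, and each track was centred on the median of its 23809 arm bins. The robust SD (1.4826 times the median absolute deviation) of bins was 0.776 and 0.474 in WT at stages 10B and 13, and 2.26 and 1.04 in H2Av[ΔCT]. A bin passed when it exceeded the track median by 4 robust SD, which was 3.11 and 1.89 in WT and 9.04 and 4.18 in H2Av[ΔCT]. Runs of at least 2 passing bins were domains, joined across gaps of up to 2 bins. Domains were shared when at least 50% of 1 was covered by the other, and 1000 random placements gave the overlap by chance. The same caller was applied to the centred difference between WT and H2Av[ΔCT].

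The named regions followed a rule set before the data were examined. They were the 6 known amplicons, each searched in a dm3 interval of 400 kb placed from general knowledge, and outside these intervals the 5 highest domains of each WT track, the 5 highest and 5 lowest domains of each genotype difference, and the 3 highest of each H2Av[ΔCT] track. Domains called only after windows without reads were removed, and the domain on 2L from 11140001, were named after their values were seen. The centre of an amplicon was the signal-weighted mean position of passing bins in the mean of both WT tracks. Its level was the mean over 100 kb around the centre, its width the length of passing bins within 200 kb of the centre, and its shape the mean at 20 to 50 kb minus the mean within 10 kb. The same measures were taken in 22055 intervals of 400 kb outside the amplicons, called random intervals. They started at every 5 kb bin, so neighbours overlap and can share a centre. Their number is therefore far above that of separate regions. Medians over the 6 amplicons were set against 10000 random sets of 6 such intervals. The median, the limits, the region classes and the alternatives were fixed before the data were examined, apart from removal of windows without reads (beyond 5 in size, or exactly 0) and 2 uses of the window median. Region classes were the heterochromatic arms, the last 1 Mb of each arm next to the centromere, 100 kb next to each telomere, chromosome 4, the X chromosome, the autosomal arms, the mitochondrial genome, and approximate intervals for the histone cluster (2L, 21400001 to 21600000) and the bithorax complex (3R, 12400001 to 12800000).

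No test between samples was possible with 1 averaged track per group, so no p-values are given. Chance overlap and random sets describe the tracks only. The caller was tested on simulated data: 40 domains of 100 kb were added to each real track. Domains raised by 3 on the log2 scale were recovered to at least 50% of their length in 100% of cases in WT at stage 13, 20% in WT at stage 10B and 0% in both H2Av[ΔCT] tracks. Domains raised by 5 were recovered in 100%, 100%, 0% (H2Av[ΔCT], stage 10B) and 82.5% (H2Av[ΔCT], stage 13). With windows without reads removed, domains raised by 3 were recovered in 100% of cases in WT at stage 13 and both H2Av[ΔCT] tracks, and 95% in WT at stage 10B. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The gene table at hand is of another genome release than dm3, so genes were not placed in domains and the planned gene lists were not analysed here.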

Results

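γH2Av is the Drosophila H2A variant phosphorylated in its C-terminal tail near DNA breaks and stalled replication forks. It was mapped by ChIP-seq in follicle cells, the somatic cells that surround the oocyte and secrete the eggshell. Late in oogenesis these cells re-replicate 6 genomic regions, the Drosophila amplicons in follicle cells (DAFC). DAFC-7F and DAFC-66D hold clusters of chorion genes, which encode eggshell proteins, and DAFC-62D holds yellow-g genes. At most of them origins fire by stage 10B and forks then move outward, while DAFC-34B and DAFC-62D are known for further origin firing at stage 13. The 16 libraries formed 8 groups of 2 replicates: ChIP and input from OregonR wild type (WT) and from H2Av[ΔCT], whose H2Av transgene lacks the tail, at stages 10B and 13. The 4 tracks analysed were the authors' mean of 2 replicates per ChIP group, so no value below has a replicate error or a p-value. Differences are set instead against random intervals or sets of intervals in the same tracks, which describe these tracks and not the spread between animals. Read depth is unknown. Windows below −5, read here as windows in which at least 1 library had no reads, made up 4.01% of arm windows in WT at stage 10B and 0.140% at stage 13. They made up 22.4% in H2Av[ΔCT] at stage 10B and 8.29% at stage 13, so the control tracks rest on the sparsest data.

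The comparison of WT with H2Av[ΔCT] asks where the signal needs the H2Av tail. At stage 13 all 6 amplicons had more γH2Av signal in WT than in H2Av[ΔCT]. The difference in mean log2 value over the 100 kb around each centre had a median of 2.02, or 4.05-fold. It was 2.75 at DAFC-62D (dm3 3L, centre 2276580), 2.71 at DAFC-34B (2L, 13409316) and 2.28 at DAFC-22B (2L, 1902483). It was 1.76 at DAFC-30B (2L, 9543063), 1.67 at DAFC-66D (3L, 8724403) and 1.59 at DAFC-7F (X, 8366898). Of 10000 random sets of 6 intervals, 44 had a median as high. At stage 10B the median difference was 0.62, or 1.53-fold, a value that 2667 of 10000 random sets reached. The difference was 1.99 at DAFC-22B, 1.73 at DAFC-62D, 1.03 at DAFC-34B, 0.20 at DAFC-30B, 0.17 at DAFC-7F and −0.03 at DAFC-66D. With windows without reads removed, a choice made after the data were examined, the medians were 1.47 at stage 10B and 2.17 at stage 13. Both then lay above the highest of 10000 random sets, 1.13 and 1.30, and the difference was above 0 at 6 of 6 amplicons at each stage. The order of the amplicons at stage 10B did not hold: the difference was then 0.93 at DAFC-22B, the lowest of the 6, 1.42 at DAFC-62D, 1.47 at DAFC-7F and DAFC-30B, 1.476 at DAFC-66D and 1.82 at DAFC-34B. Without centring, which shifts all 6 alike, it was 2.07 at DAFC-30B, 2.05 at DAFC-7F and 1.85 at DAFC-66D.

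The level of each amplicon, relative to the median of its own track, shows how the genotypes contributed. In WT at stage 13 the 6 levels had a median of 3.20, or 9.19-fold above the track median. DAFC-34B had the highest level at 3.59, DAFC-62D, DAFC-66D and DAFC-7F had 3.21, 3.21 and 3.19, DAFC-30B had 2.99 and DAFC-22B had 2.12. Each of the 6 exceeded every one of 22055 overlapping random intervals, whose highest level was 1.96. In WT at stage 10B the levels were 2.27 at DAFC-34B, 2.01 at DAFC-62D, 1.99 at DAFC-7F, 1.78 at DAFC-30B and 1.75 at DAFC-66D. These 5 amplicons lay above the central 95% of random intervals, which ended at 1.40, and DAFC-22B, at 0.91, did not. In H2Av[ΔCT] the levels at stage 13 were 1.59 at DAFC-7F, 1.54 at DAFC-66D, 1.23 at DAFC-30B and 0.87 at DAFC-34B, above the upper end of 0.82, and 0.46 at DAFC-62D and −0.16 at DAFC-22B. At stage 10B they were 1.82 at DAFC-7F, 1.78 at DAFC-66D, 1.58 at DAFC-30B, 1.24 at DAFC-34B, 0.28 at DAFC-62D and −1.09 at DAFC-22B. Windows without reads in H2Av[ΔCT] at stage 10B were rarer than over all arms at 5 of 6 amplicons, DAFC-66D (2.12%), DAFC-7F (4.14%), DAFC-30B (4.55%), DAFC-34B (8.69%) and DAFC-62D (18.8%), and were 28.1% of windows at DAFC-22B. With them removed, the H2Av[ΔCT] levels ranged from 0.05 to 0.40 at stage 10B and from 0.07 (DAFC-22B) to 1.15 (DAFC-7F) at stage 13.

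**Figure D1:**
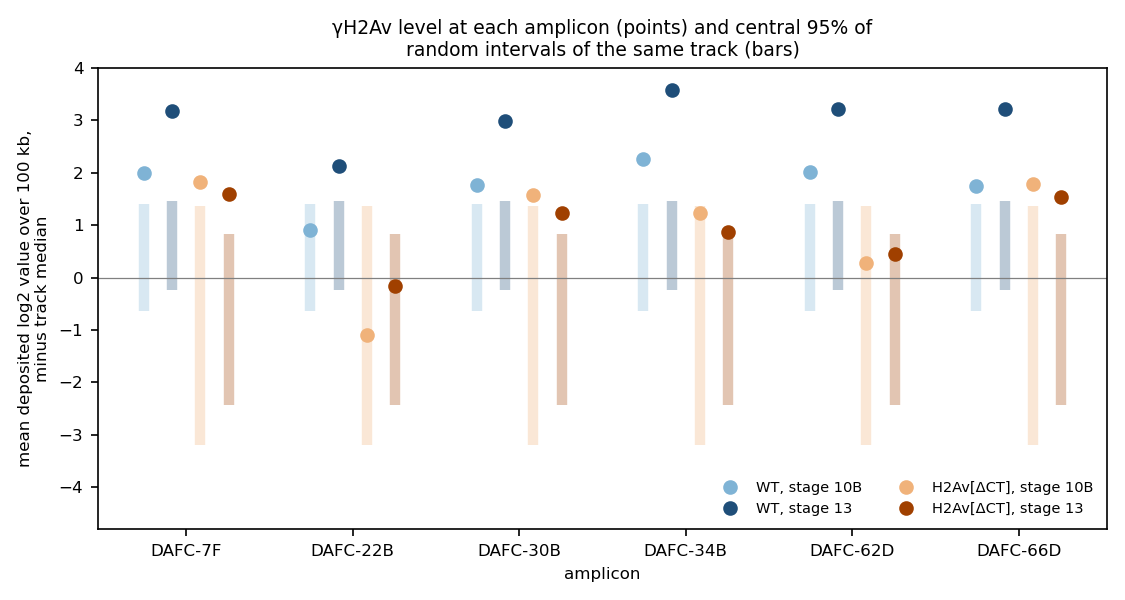
Mean deposited log2 value over 100 kb at each amplicon, minus the track median (points; vertical axis, log2), for the 4 tracks, with bars for the central 95% of random intervals of the same track. WT at stage 13 has the highest point at every amplicon, between 2.12 and 3.59, above every random interval.

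The comparison of stages asks how the signal changes as amplification proceeds. In WT all 6 amplicons had more γH2Av signal at stage 13 than at stage 10B, by a median of 1.22 on the log2 scale, or 2.32-fold. The difference was 1.46 at DAFC-66D, 1.32 at DAFC-34B, 1.22 at both DAFC-30B and DAFC-22B, 1.20 at DAFC-62D and 1.19 at DAFC-7F. None of 10000 random sets reached this median, and the highest was 0.91. Within 5 kb of the centre the median WT level over the 6 amplicons was 2.97 at stage 13 and 2.11 at stage 10B. At 40 to 50 kb it was 2.19 and 1.02, and at 75 to 100 kb it was 1.03 and 0.16. At 150 to 200 kb it was 0.06 at stage 13 and −0.34 at stage 10B, but 0.05 and −0.02 with the window median. The highest single bins at stage 13 were 4.97 in DAFC-66D (3L, 8710001 to 8715000) and 4.81 in DAFC-34B (2L, 13395001 to 13400000). In H2Av[ΔCT] the median stage difference over the amplicons was −0.23, with 2 of 6 above 0, and 6512 of 10000 random sets were as high. With windows without reads removed it was 0.49, above 0 at 5 of 6 amplicons and above the highest random set (0.46), against 1.40 in WT.

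The width and shape of the amplicon signal were compared next. The bins above the calling limit covered 150 kb at DAFC-62D, 125 kb at DAFC-34B, 120 kb at DAFC-7F, 110 kb at DAFC-30B, 105 kb at DAFC-66D and 65 kb at DAFC-22B in WT at stage 13. At stage 10B they covered 15 kb at DAFC-34B and 10 kb at DAFC-66D, and no bin passed at the other 4 amplicons. These widths were not measured at equal sensitivity, because the limit was 3.11 above the track median at stage 10B and 1.89 at stage 13. Whether the signal moved from the centre (within 10 kb) to the flanks (20 to 50 kb) could not be decided. The flank minus centre value was higher at stage 13 by a median of 0.24, and 6625 of 10000 random sets were at or above that value. Random intervals without passing bins, however, were centred on their highest 20 kb mean in WT, which lowers their flank minus centre values. Their own stage difference had a median of 0.29, so they are no neutral reference for this measure.

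**Figure D2:**
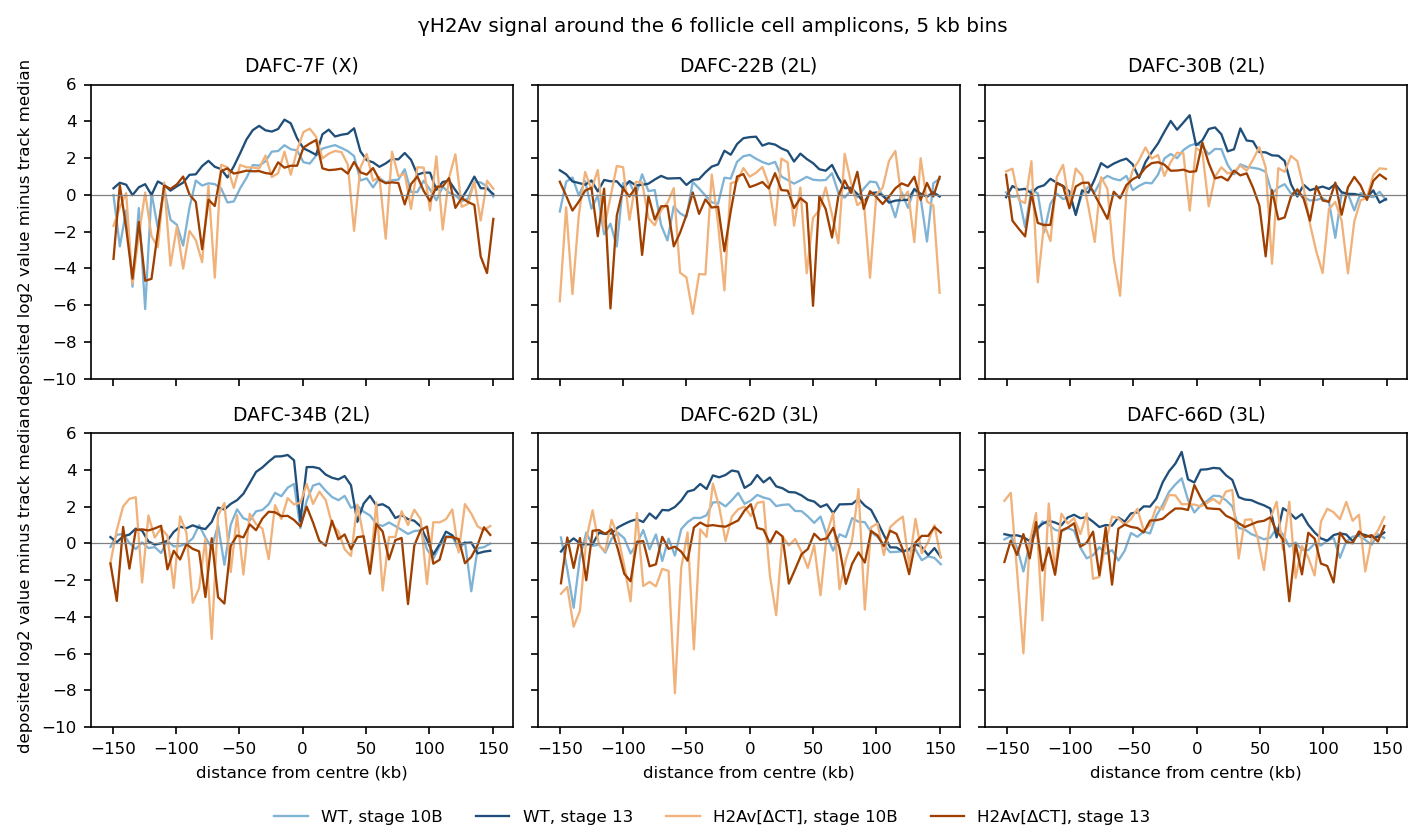
Deposited log2 value minus the track median (vertical axis) in 5 kb bins against distance from the centre of each amplicon in kb (horizontal axis), 1 line per track and 1 panel per amplicon. WT at stage 13 is raised over a broad region at each amplicon, with dips near the centre at most of them and a highest bin of 4.97 at DAFC-66D. The H2Av[ΔCT] lines dip far below 0 where windows had no reads.

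Domains were called across the arms X, 2L, 2R, 3L and 3R to find other regions with high signal. In WT at stage 13 there were 21 domains spanning 950 kb, of which 7 lay in the amplicon intervals, covered 680 kb and included all 6 amplicons. The largest amplicon domains were at DAFC-62D (3L, 2215001 to 2370000, mean 2.82) and DAFC-34B (2L, 13350001 to 13480000, mean 3.27). The 14 domains outside the amplicons covered 270 kb. The highest was on X (18550001 to 18585000), with a mean of 2.85 at stage 13 and 1.52 at stage 10B in WT, and 0.53 and 0.24 in H2Av[ΔCT]. The next was on 2L (5940001 to 5980000), with 2.77 at stage 13 and 1.20 at stage 10B in WT, and 0.53 and 1.56 in H2Av[ΔCT]. After removal of windows without reads its stage 10B levels were 1.15 in WT and −0.005 in H2Av[ΔCT], which turns the direction of the difference. Domains on 3L (24220001 to 24230000, mean 2.42) and X (20885001 to 20900000, mean 2.08) were already at 2.90 and 2.34 in WT at stage 10B. A domain on 3R (8330001 to 8340000) had a mean of 2.11 in WT at stage 13 but 3.98 in H2Av[ΔCT], and 1.86 and 4.87 at stage 10B. In WT at stage 10B there were 2 domains, at DAFC-34B (2L, 13415001 to 13425000) and DAFC-66D (3L, 8705001 to 8715000). Both lay within WT stage 13 domains, whereas random placements of the same lengths gave a mean of 0.021 such overlaps. No domain was called in H2Av[ΔCT] at either stage, but the calls were not equally sensitive. Simulated domains of 100 kb raised by 3 were recovered in 100% of cases in WT at stage 13, in 20% in WT at stage 10B and in 0% in both H2Av[ΔCT] tracks. After removal of windows without reads, WT had 13 domains at stage 10B, in 5 of the 6 amplicons and elsewhere, and 24 at stage 13, whereas H2Av[ΔCT] had 1 at stage 10B and 12 at stage 13, the latter with DAFC-7F and DAFC-66D among them.

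Domains were also called on the difference between WT and H2Av[ΔCT], where the limit was 5.24 at stage 13 and 8.82 at stage 10B. At stage 13, 58 domains spanning 1155 kb were higher in WT and 1 was lower, and none lay in the amplicon intervals. Their absence there says little, because the highest amplicon bin in WT at stage 13 was 4.97. A bin there could pass as higher in WT only where H2Av[ΔCT] lay below its own track median. The 58 had a median level of 1.28 in WT and −5.89 in H2Av[ΔCT], where a median of 53.8% of their windows had no reads. The highest difference was on 2L (17185001 to 17195000), at 2.03 in WT and −8.76 in H2Av[ΔCT]. The others with the highest differences were on X (12175001 to 12185000; 1.30 and −8.01), 3L (13750001 to 13775000; 1.71 and −7.59), 2L (4520001 to 4530000; 0.05 and −9.22) and 3L (24110001 to 24125000; 1.08 and −8.17). The lower domain was next to a telomere on 3L (30001 to 45000), at −6.59 in WT and 0.31 in H2Av[ΔCT]. With windows without reads removed the difference there was 0.48. The removal had to take out the WT values behind this call, since only windows below −5 can give so low a mean. The sign of the remaining difference is therefore no evidence of higher signal in WT. At stage 10B, 6 domains were higher in WT and none was lower, with a median of 81.9% of windows without reads in H2Av[ΔCT]. The highest difference was on 2L (17025001 to 17035000), at 2.22 in WT and −10.13 in H2Av[ΔCT]. The next had levels of −8.40 in H2Av[ΔCT] on 2L (16005001 to 16015000), −9.48 on X (12035001 to 12045000), −8.44 on 3R (3475001 to 3485000) and −8.37 on 3L (4950001 to 4960000). After windows without reads were removed, 8 domains were higher in WT at stage 13, 1 in each of the 6 amplicons and 2 outside, on 2L (5955001 to 5970000) and X (18560001 to 18575000). None of the 58 domains was covered by these 8, but removal takes out the control windows with the lowest values, from which the 58 were called. At stage 10B 1 domain was called, on 2L (11775001 to 11785000).

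Heterochromatin, which is under-replicated in polyploid follicle cells, and other region classes were compared by the median of their 5 kb bins. The 6 heterochromatic arms had levels of 1.15 at stage 10B and 0.53 at stage 13 in WT, and −0.58 and −0.77 in H2Av[ΔCT]. WT exceeded H2Av[ΔCT] there by 1.56 at stage 10B and 1.49 at stage 13, and by 0.76 and 0.67 with windows without reads removed. The median bin difference of stage 13 minus stage 10B on these arms was −0.56 in WT, opposite in direction to the amplicons, and −1.29 in H2Av[ΔCT]. The H2Av[ΔCT] value was 0.13 without centring, −0.36 with the median of windows per bin and −0.40 with windows without reads removed, and the WT value was −0.65, −0.45 and −0.55. On these arms 12.9% of H2Av[ΔCT] windows at stage 10B were listed at exactly 0, and centring alone gives bins of such windows a stage difference of −1.42, the median on 2LHet, 2RHet and 3RHet. The 1 Mb next to the centromeres had levels of 1.09 and 0.63 in WT, with differences from H2Av[ΔCT] of 0.78 and 0.79, or 0.70 and 0.73 with the window median. By arm the main differences were 3.07 and 2.18 on 3L, 1.24 and 1.07 on 2L, 0.86 and 0.76 on X, and 0.47 and 0.58 on 2R. On 3L 34.9% and 17.2% of H2Av[ΔCT] windows had no reads, and the differences were 1.70 and 1.34 with the window median. With the window median they were 1.18 and 1.07 on 2L, 0.63 and 0.74 on X, and 0.57 and 0.45 on 2R. On 3R the differences had the opposite sign, −1.02 and −0.24, or −0.18 and −0.04 with the window median. Among these regions the WT stage 10B level was highest on 3L (1.60) and lowest on 3R (0.26). Chromosome 4 had levels of 0.88 at stage 10B and 0.17 at stage 13 in WT, with differences from H2Av[ΔCT] of −0.37 and 0.12. The stage 10B difference turned to 0.84 with windows without reads removed, 0.43 with the window median and 1.51 without centring. The histone gene cluster had levels of 0.79 and 0.26 in WT, with differences of −1.72 and −0.27, of which the first was 0.021 after removal, −0.43 with the window median and 0.15 without centring, and the second was 0.16, 0.10 and 0.09. The bithorax complex of homeotic genes had levels of −0.38 and −0.16 in WT, with differences of 2.48 and 1.17 where 47.0% and 13.8% of H2Av[ΔCT] windows had no reads. With these windows removed the bithorax differences were 0.15 and 0.11. The 100 kb next to the telomeres had WT levels of 0.07 and 0.02 and differences of −0.89 and −0.09, of which the first was 0.34 after removal, −0.10 with the window median and 0.99 without centring, and the second was 0.15, 0.03 and 0.28. The X chromosome and the autosomal arms had WT levels within 0.02 of the track median at both stages. The mitochondrial genome, covered by 4 bins, had WT levels of −2.52 and −3.66 and differences of −1.63 and −1.45, of which the first was 0.11 after removal, −0.23 with the window median and 0.24 without centring, and the second was −1.02, −1.08 and −1.08.

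**Figure D3:**
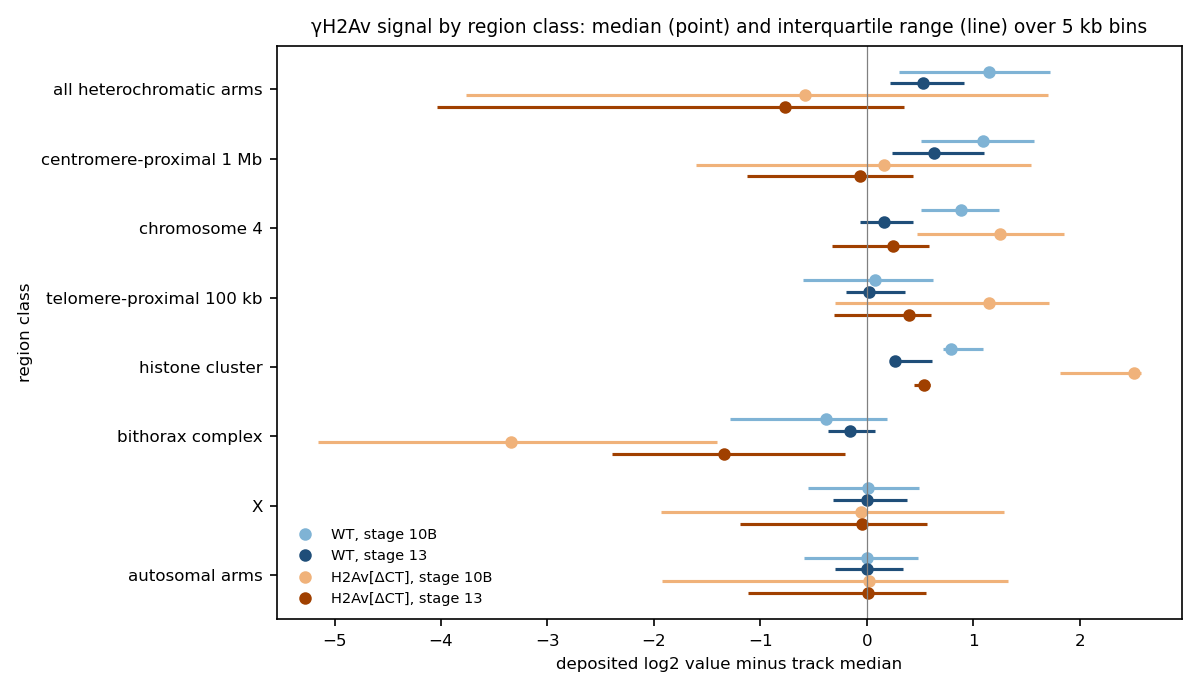
Median (points) and interquartile range (lines) of the deposited log2 value minus the track median over 5 kb bins (horizontal axis) for 8 region classes (vertical axis) in the 4 tracks. Heterochromatic arms and centromere-proximal regions lie above 0 in WT, at 1.15 and 1.09 at stage 10B. The H2Av[ΔCT] line of the heterochromatic arms at stage 10B runs from −3.77 to 1.70.

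Across 23809 bins, which are not independent replicates, the WT tracks of the 2 stages had a Pearson correlation of 0.505 (Spearman 0.592). WT and H2Av[ΔCT] had correlations of 0.101 at stage 10B and −0.124 at stage 13 (Spearman 0.0904 and −0.0995). Removing windows without reads gave 0.743 between the WT stages, 0.148 between genotypes at stage 10B and 0.0382 at stage 13. Leaving out the amplicon intervals gave 0.501, 0.0936 and −0.166.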

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

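Every test of an explanation below was chosen after the result it bears on had been seen, and so was the removal of windows without reads. Differences between genotypes or stages in this part were not themselves tested, because each group is 1 averaged track.

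The stage effect had opposite signs in the genotypes at 4 amplicons, but each H2Av[ΔCT] value was closer to 0 than the SD of random intervals (0.69). At DAFC-66D the stage effect was 1.46 in WT and −0.24 in H2Av[ΔCT], values that differ by 1.70. At DAFC-34B the effects were 1.32 and −0.36 and differ by 1.68, at DAFC-30B they were 1.22 and −0.34 and differ by 1.56, and at DAFC-7F they were 1.19 and −0.23 and differ by 1.42. At DAFC-66D the genotype effect was 1.67 at stage 13 and near 0 at stage 10B (−0.03, against an SD of 1.36 in random intervals), again a difference of 1.70. On chromosome 4 it was 0.12 at stage 13 and −0.37 at stage 10B, a difference of 0.49, and both values were within the SD of medians over 1 Mb regions of the arms (0.58 and 0.82). With windows without reads removed, the H2Av[ΔCT] stage effect was above 0 at these amplicons (1.02, 0.33, 0.65 and 0.78 in the same order), and the genotype effect at stage 10B was above 0 at DAFC-66D (1.476) and on chromosome 4 (0.84).

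H2Av[ΔCT] lacks the tail that carries the phosphate, yet its tracks lay above their medians at most amplicons. Fewer windows without reads over amplified DNA do not account for this at stage 13: with them removed the median level over the amplicons was 0.70, above the highest of 10000 random sets (0.37). At stage 10B the median after removal was 0.22, which 114 of 10000 random sets reached, so this explanation cannot be told apart from a small remaining signal there. A residual mark, for example from wild-type H2Av supplied by the balancer chromosome in the labelled genotype, may remain. It was tested by shape: the level within 5 kb of the centre minus that at 5 to 20 kb had a median of −0.54 in WT and 0.95 in H2Av[ΔCT] at stage 13. This value was above 0 at 4 of 6 amplicons in H2Av[ΔCT] and at 1 of 6 in WT, so neither track had 1 shape at all amplicons. The residual mark therefore stays open. Background in proportion to DNA copy number would be divided out if the values are ChIP over input, as inferred here. Background of another kind was not tested.

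The 58 domains higher in WT at stage 13 had their low values in H2Av[ΔCT], and after removal of windows without reads 0 of the 58 were covered by a called domain and the median difference went from 6.84 to 1.26. In 58 of 58 the control mean before centring lay below −5, a value that only windows below −5 can give. The low control values behind these calls therefore came from windows without reads, and the removal had to take them out. The loss of coverage is thus no separate test, and the remaining 1.26 has no firm size. Why these windows lacked reads stays open. Higher γH2Av signal in WT in the same regions may contribute. The WT stage 10B track, which took no part in the calls, had a median level of 1.25 over them after removal. The highest of 10000 random sets of the same lengths had 0.33. This is not independent evidence, because that track had a correlation of 0.743 after removal with the WT stage 13 track used in the calls. The random sets were not matched on WT stage 13 level. Late replication or a lower DNA copy number of these regions was not tested.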

How the results depend on the processing

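Removal of windows without reads, and the window median for region classes and correlations, were chosen after the data were examined. All other alternatives were chosen before. Of the alternative values for the main results, 134 stayed within 1 SD or 1.5 times a count, 77 moved beyond that and 6 changed sign. Of those for single amplicons, regions and domains, 449 stayed, 179 moved and 18 changed sign. The SD was that of medians of random sets of 6 intervals for amplicon medians, and of random intervals for single amplicons and domains. It was that of medians over 1 Mb for region classes, and of arms for correlations. In both groups of values a change of sign was counted only where the main value was larger in size than its SD. Smaller main values that changed sign, such as the H2Av[ΔCT] stage difference over the amplicons, are among those that stayed or moved. The amplicons had higher signal in WT at stage 13 than at stage 10B, and than in H2Av[ΔCT] at stage 13. Both directions held under each alternative run, with lowest medians of 0.83 and 1.23. The highest medians, 4.76 and 6.15, came from division by robust SD. In that setting each centred track was divided by its robust SD and multiplied by the mean robust SD of the tracks. Its values are therefore not log2 differences and cannot be compared in size with the others. The SD used to count its values as moved was not rescaled. Unless a sentence states a cause, the cause was not tested.

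Counts of domains moved with the limit by construction. In the order WT stage 10B, WT stage 13 and higher at stages 10B and 13 in the genotype difference, the limit of 3 robust SD gave 15, 74, 62 and 125 (and 3 in H2Av[ΔCT] at stage 13), and 6 robust SD gave 0, 9, 0 and 19 (and 0 lower at stage 13). The fixed limit of 0.5 gave 748, 369, 1266 and 1070, with 1235 and 954 in H2Av[ΔCT] and 1332 and 1039 lower at stages 10B and 13. Bins of 1 kb gave 0, 9, 0 and 3, with 0 lower at stage 13. Bins of 10 kb gave 50 in WT at stage 13 and 41 higher at stage 10B. A minimum of 1 bin gave 4, 51, 100 and 276, with 2 in H2Av[ΔCT] at stage 13. The window median gave 6 in WT at stage 10B, 7 in H2Av[ΔCT] at stage 13, and 439 higher and 1 lower at stage 10B. Removing windows without reads gave 13 in WT at stage 10B, 1 and 12 in H2Av[ΔCT] at stages 10B and 13, 1 and 8 higher at stages 10B and 13, and 0 lower at stage 13. With a shared domain defined by 1 base, 2 WT stage 13 domains were shared with stage 10B.

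The amplicon median of WT minus H2Av[ΔCT] at stage 10B was 1.495 in 1 kb bins, 1.97 with tracks divided by their robust SD, 1.36 with the window median, 2.49 without centring and 1.47 with windows without reads removed. It was 1.03 without DAFC-7F, DAFC-30B or DAFC-66D, and 0.20 without DAFC-22B, DAFC-34B or DAFC-62D. At stage 13 it was 6.15 with tracks divided by their robust SD and 1.23 over the whole 400 kb. The WT stage difference was 1.35, 4.76, 1.37 and 1.40 in 1 kb bins, with division by robust SD, with the window median and after removal, and 0.83 over 400 kb. The H2Av[ΔCT] stage difference was above 0 under 6 alternatives: 0.43 in 1 kb bins, 0.10 over 200 kb, 0.34 with division, 0.47 with the window median, 1.19 without centring and 0.49 after removal. The gain in width was 86.5 kb, 90 kb and 85 kb in 1 kb bins, with the window median and after removal. The flank minus centre change was −0.10 with the centre at the highest 20 kb and −0.27 with division. All values with division are on the rescaled tracks and are not log2 differences, so only their signs can be set beside the others.

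Without centring, the H2Av[ΔCT] stage 10B levels were −0.36, −0.60, −0.95 and −0.40 at DAFC-7F, DAFC-30B, DAFC-34B and DAFC-66D, since that track has a median below 0. Over 400 kb the H2Av[ΔCT] levels were −0.040 and −0.24 at stage 10B and −0.12 and −0.19 at stage 13 at DAFC-7F and DAFC-30B.

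For heterochromatic arms, WT minus H2Av[ΔCT] was 3.44 at stage 10B without centring, and at stage 13 it was 2.69 with the mean over bins and 0.67 after removal, where the H2Av[ΔCT] level was 0.014. Their H2Av[ΔCT] stage difference was −0.74 in 1 kb bins, −0.85 with the mean over bins, −0.36 with the window median, 0.13 without centring and −0.40 after removal. For the centromere-proximal regions it was −0.28 with the mean over bins, −0.27 with the window median, 0.75 without centring and −0.13 after removal, and WT minus H2Av[ΔCT] at stage 10B was 2.65 without centring. Genotype differences at stage 10B changed sign without centring and after removal at the mitochondrial genome (0.24 and 0.11), the telomere-proximal regions (0.99 and 0.34) and the histone cluster (0.15 and 0.021). The WT levels were −0.13 at the histone cluster at stage 13 without centring and 0.054 at the bithorax complex at stage 10B after removal. The domain lower in WT on 3L from 30001 had a difference of 0.48 after removal, which takes out the WT windows behind its call.

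The correlation between WT stages was 0.298 and 0.589 in bins of 1 and 10 kb, 0.595 with the window median and 0.743 after removal. Between genotypes it was −0.0451 at stage 10B with the window median and 0.0382 at stage 13 after removal. No paired analysis was possible because the tables hold means of the replicates, and for the same reason leaving out each replicate and the replicate block were not run. The correction for GC content and the gene lists were not run, since no genome or annotation of dm3 was used here. Restricting to windows present in all 4 tables changes nothing, because all 4 list the same windows.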

Other observations

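The tests in this part were chosen after the values had been seen, as was the minimum length of 30 kb. The domains of WT at stage 13 outside the amplicons did not all follow the same course between the stages. The 3 domains of at least 30 kb, on X (18550001 to 18585000), 2L (5940001 to 5980000) and 2L (11140001 to 11190000), had WT levels of 2.85, 2.77 and 1.98 at stage 13 against 1.52, 1.20 and 0.98 at stage 10B. With windows without reads removed they were higher at stage 13 by 1.03 to 1.61, as the amplicons were by 1.20 to 1.64, whereas the 11 shorter domains ranged from −0.30 to 1.098. The first 2 are also the domains outside the amplicons that were called on the difference between WT and H2Av[ΔCT] after that removal.

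The values argue against background shared with the control as the source of these 3 domains, since the highest H2Av[ΔCT] level at stage 13 among them was 0.37 after removal. Windows without reads in WT at stage 10B do not account for the change either. They made up at most 1.43% of windows in these domains, against 4.01% over all arms, and the smallest stage difference after removal was 1.03. That is above 2 SD of random intervals (0.48), but those were 100 kb regions not selected for a high stage 13 level, so the SD is only a rough guide. A hypothesis is that these regions may gain DNA copies in the same cells, which would leave fewer windows without reads in the control. That held in both H2Av[ΔCT] tracks at 2 of the 3 domains, with 2.56% and 1.28% of windows on 2L from 5940001 and 14.4% and 2.05% on X, against 22.4% and 8.29% over all arms. The 2L domain from 11140001 had 32.4% and 4.89%, so the hypothesis stays open, and DNA copy number itself was not analysed here.

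The WT stage 13 domain on 3R (8330001 to 8340000) had no windows without reads in H2Av[ΔCT] and levels of 2.94 and 3.07 there at stages 10B and 13 after removal, above the WT levels of 1.68 and 2.10. The WT stage 13 domains included 5 between 16920001 and 17250000 on 2L, where the H2Av[ΔCT] track at stage 13 had between 12.9% and 74.7% of windows without reads.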
